A study of Homo sapiens with 9 samples.

How the data were processed

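The data were 9 total RNA libraries of the AHH-1 line, 3 per dose at 0 (sham), 2 and 5 Gy of 60Co γ-rays given at 1 Gy per min and collected after 4 h, per the labels. The replicate numbers are not stated to mark a shared culture or day. Over 9 same-number pairs from different doses the correlation of residuals lay between -0.0606 and 0.0491, and a replicate block was an alternative.

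The deposited count table holds a whole back-splice read count per circRNA and library. The deposited CPM table holds CPM values after TMM scaling by the authors for 110 circRNAs, and each value equals the count divided by 1 constant per library. That constant implies library totals of 32352653 to 58711737 reads, which include the authors' TMM factors and are thus effective totals. A log10 column of mean expression comes with the deposited CPM table. The authors' tables for 2 and 5 Gy against 0 Gy give a log2 fold change, a fold (ratio) equal to 2 to that power, and a p-value with its adjusted p-value. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.8a, edgeR without a version and the hg19 build. The circRNA caller and the filters of the authors are not given in the sources used here. Every listed circRNA had at least 2 reads in some library. Starts in the count table were 0-based, since end minus start equalled the spliced length for 682 circRNAs and never when 1 was added; positions are printed as 1-based hg19. Of 7359 circRNAs whose host name is in the GRCh38 gene table, 1179 (16.0%) lay inside that gene at GRCh38 positions, so that build was not used for positions.

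All 7902 circRNAs entered library totals and shares, including 430 with no host gene named (3.47% of reads), which are junctions with their own positions. Between 2742 and 5201 back-splice reads per library set the precision: a circRNA at 2 per 1000 had about 5 to 10 reads, and all 9 same-dose pairs differed by more than sampling (chi-square over degrees of freedom 1.22 to 1.63, p 8.81e-07 to 0.0273, circRNAs with at least 25 reads in all). In CPM of the implied totals, back-splice reads made up 84.8 to 100.

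Comparisons and tests below were fixed before the data were examined, except where stated. edgeR 4.0.16 in R 4.3.3 fitted all 9 libraries by dose group with TMM scaling, filterByExpr at its defaults (minimum count 10, minimum total 15, 28 circRNAs kept), and the quasi-likelihood F test, adjusted by Benjamini-Hochberg over the circRNAs tested with a threshold of 0.05. The trend used the dose in Gy as a number. Host genes were tested on summed counts (58 kept). Levels per 1000 are reads per 1000 TMM-scaled back-splice reads. The 738 circRNAs with at least 2 reads in at least 3 libraries hold 42.1% of the reads and formed the planned wider filter. Library measures used two-sided exact permutation tests over the 1680 arrangements of the libraries into doses, or over single pairs of doses, where the smallest p is 0.1. Libraries were thinned to 2742 reads (100 draws). Of 11 fixed lists, camera and fry of limma 3.58.1 tested those with at least 5 tested circRNAs, camera with a preset correlation of 0.01: p53 targets, DNA damage signalling and repair, cell cycle and mitosis, chromatin modifiers, RNA processing, ubiquitin ligases and deubiquitinases, NF-κB and innate immune signalling, B-lymphoid genes, T and NK cell genes, myeloid genes, and hosts of widely reported circRNAs. The T and NK and myeloid lists had too few circRNAs for a set test.

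The shared 0 Gy libraries were modelled with 100 simulations of unchanged groups with the filter applied again; that step was added after a first version, and 811 circRNAs passed it on average against 738 observed. The fit was tested on simulated data for 5 against 0 Gy (20 simulations): it recovered 50.0, 95.0 and 100% of 2-, 4- and 8-fold changes among the 28, and 1.27, 13.1 and 40.0% among the 738, with 0.20 and 0.45 false calls per simulation.

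Alternatives were DESeq2 1.42.0 size factors and Wald test, no scaling factor, no filter, the edgeR exact test, fits of 2 doses alone, a replicate block and leaving out each library. Chosen after the data were seen were the library sizes implied by the deposited CPM, the minimum count in 2 instead of 3 libraries, DESeq2 on the 738, refits over the circRNAs of the deposited tables, thinning followed by a second filter, camera with estimated correlation on the 738, back-splice reads as CPM of the implied totals, the junction classes, the list shares and the usage tests within host genes. Usage was tested with edgeR's splicing test over 113 host genes with several circRNAs among the 738. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 gave the other values.

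Named circRNAs followed a fixed rule: for 2 and 5 Gy against 0 Gy those past the threshold, filled up to 24 with the smallest p, the 3 of smallest p per list, and the 5 of smallest p per direction in the authors' differential tables. For 5 against 2 Gy and the trend the 5 of smallest p were eligible, over all libraries the 6 of highest mean level, and for host genes the 5 of smallest p. Values are printed for those that matter most among them. MALAT1 fell under the host-gene rule. XPO1 hsa_circ_0001017 fell under the rule, but setting it beside hsa_circ_0001016, and ZFAND6 in the usage test, were chosen after their values were seen.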

Results

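Circular RNAs, closed loops formed when a splice donor joins an upstream acceptor, were counted in AHH-1 human B-lymphoblastoid cells 4 h after 0 (sham), 2 or 5 Gy of 60Co γ-rays, with 3 libraries per dose. The 9 libraries held 38147 back-splice reads on 7902 circRNAs. They came from 3521 named host genes, apart from 430 circRNAs with no host gene named. Libraries ranged from 2742 to 5201 back-splice reads. ZNF124 hsa_circ_0112879 (chromosome 1, 247319708 to 247323115), a circRNA with 234 reads over 9 libraries, had the highest mean level. The data were sparse: 4791 circRNAs were seen in 1 library only, 133 were seen in all 9, and 28 had enough reads for the planned test, holding 8.35% of all reads. The series asks which circRNAs differ with dose and whether they can separate doses.

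None of the 6 most abundant circRNAs passed the test at 2 or 5 Gy. ZNF124 hsa_circ_0112879 stood at 5.49 ± 0.0347, 6.69 ± 1.35 and 6.10 ± 1.64 reads per 1000 back-splice reads after 0, 2 and 5 Gy (mean ± SD, n = 3 libraries, as for all levels below). HIPK3 hsa_circ_0000284 (chromosome 11, 33307959 to 33309057), a large single-exon circle of a serine/threonine kinase gene, stood at 5.09 ± 2.22, 6.74 ± 1.04 and 5.13 ± 1.34. GUSBP1 hsa_circ_0128780, whose host is a pseudogene with near-identical copies so that its reads cannot be placed with certainty, stood at 4.81 ± 2.39, 4.59 ± 1.02 and 5.79 ± 1.29. CDYL hsa_circ_0008285 stood at 4.21 ± 1.5, 4.44 ± 1.12 and 4.58 ± 0.707, and MAN1A2 hsa_circ_0000118 at 4.25 ± 0.514, 4.57 ± 0.585 and 4.01 ± 1.25. TET2 hsa_circ_0070562 (chromosome 4, 106155054 to 106158508), from the gene of a 5-methylcytosine dioxygenase, stood at 3.34 ± 0.279, 4.07 ± 0.394 and 4.79 ± 0.684. Its log2 fold change at 5 Gy was 0.53 (SE 0.33, edgeR p 0.106). Together the 10 most abundant circRNAs took 4.14 ± 0.530, 4.10 ± 0.174 and 4.31 ± 0.347% of the reads at 0, 2 and 5 Gy.

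At 2 Gy the lowest p-values among the 28 tested circRNAs belonged to circRNAs with fewer reads than at 0 Gy, and none passed. NR3C1 hsa_circ_0001543, from the glucocorticoid receptor gene, stood at 3.50 ± 1.76 and 1.82 ± 1.25 per 1000 at 0 and 2 Gy, a log2 fold change of -0.79 (SE 0.43, p 0.0688). It was -0.37 without 0 Gy replicate 1, -0.45 without 2 Gy replicate 2 and -1.48 without 2 Gy replicate 3 (adjusted p 0.296). FBXW7 hsa_circ_0001451 (chromosome 4, 153332455 to 153333681), from the gene of a ubiquitin ligase subunit that p53 induces, stood at 3.76 ± 0.651 and 2.27 ± 0.694, a log2 fold change of -0.73 (SE 0.40, p 0.0690; -0.45 without 2 Gy replicate 3). KANSL1 hsa_circ_0005455 had -0.53 (SE 0.35; -0.29 without 0 Gy replicate 2), and ZBTB44 hsa_circ_0002484 had 0.63 (SE 0.48) and 0.17 without 2 Gy replicate 2. edgeR called 0 of 28 circRNAs at 2 against 0 Gy, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.951, and DESeq2 and the edgeR exact test, the latter over 21 circRNAs, also called 0, with 0 and 0 at that level. Of the 28, 12 were higher and 16 lower at 2 Gy, and 1 had groups that did not overlap, where chance gives 10%. The median SE was 0.43 in log2, and for 5 against 0 Gy a fit on simulated data recovered 50% of 2-fold changes.

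PCMTD1 hsa_circ_0001801 (chromosome 8, 52773405 to 52773806, minus strand, exon-exon, 402 nucleotides) had too few reads for the 28 but had the lowest p at 2 Gy in a wider set. Its host encodes a protein with an isoaspartate methyltransferase domain. It had 1, 4 and 2 reads at 0 Gy, 12, 7 and 15 at 2 Gy, and 7, 2 and 2 at 5 Gy, or 0.616 ± 0.368, 2.66 ± 0.748 and 0.780 ± 0.636 per 1000. Among the 738 circRNAs with at least 2 reads in at least 3 libraries, its level at 2 Gy was 3.97-fold that at 0 Gy (log2 1.99, SE 0.63), with an unadjusted edgeR p of 0.00169 and an adjusted p of 0.846. The log2 difference between 5 and 2 Gy was -1.71 (SE 0.58, p 0.00308, adjusted p 0.990), and between 5 and 0 Gy 0.28 (SE 0.75, p 0.710), with -0.41 without 5 Gy replicate 1 and 0.84 without 0 Gy replicate 2. All 3 libraries of 2 Gy lay above all 3 of 0 Gy. Among the 738, edgeR called 0 at 2 Gy, with 37 at an unadjusted p under 0.05 (27 higher, 10 lower) where 36.9 are expected by chance, and DESeq2 called 0 with 9 at that level; 68 had groups that did not overlap, where chance gives 10%.

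Whether PCMTD1 hsa_circ_0001801 passed depended on the filter and on which library was left out. With the minimum count asked for in 2 instead of 3 libraries, a filter chosen after the data were seen, 36 circRNAs were tested and it alone was called at 2 Gy (log2 1.95, SE 0.55, adjusted p 0.0381). The adjusted p for 5 against 2 Gy was then 0.0572. Leaving out 1 library also lowers that minimum to 2 libraries, and it was called at 2 Gy without 0 Gy replicate 2, 2 Gy replicate 2, or 5 Gy replicate 1, 2 or 3 (adjusted p 0.0245, 0.0380, 0.0128, 0.0446 and 0.0132). No circRNA was called at 2 Gy by edgeR without 0 Gy replicate 1 or 3 or 2 Gy replicate 1 or 3, where 3, 1, 0 and 1 had an unadjusted p under 0.05 and the smallest adjusted p was 0.170, 0.255, 0.694 and 0.397. PCMTD1 hsa_circ_0001801 met the minimum count only in 2 Gy replicates 1 and 3. It thus entered these sets through the dose where it was high, and the adjusted p-values are not independent support. Without 2 Gy replicate 1 or 3 it had too few reads to be tested. It was called between 5 and 2 Gy without 0 Gy replicate 2 or 3, 2 Gy replicate 2 or 5 Gy replicate 1 (adjusted p 0.0374, 0.0362, 0.0450 and 0.00745), and without the other 5 libraries the smallest adjusted p lay between 0.0689 and 0.542. Over the 71 circRNAs that the authors' deposited table lists, edgeR gave it an adjusted p of 0.0625 with the library sizes behind the deposited CPM, and 0.0788 with the exact test. Starting from the 738, its adjusted p at 2 Gy ranged from 0.581 to 0.994 over 15 alternatives.

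At 5 Gy the lowest p among the 28 was that of XPO1 hsa_circ_0001016, which was lower (chromosome 2, 61749746 to 61753656, minus strand, exon-exon), from the gene of the nuclear export receptor exportin 1. It stood at 2.91 ± 1.76, 2.27 ± 0.963 and 1.01 ± 0.687 per 1000 after 0, 2 and 5 Gy, 0.362-fold at 5 against 0 Gy (log2 -1.47, SE 0.54, edgeR p 0.00742, adjusted p 0.208), and without 0 Gy replicate 1 the log2 was -0.91. The other tested circle of XPO1, hsa_circ_0001017 (61749746 to 61761038), which shares one end with it, stood at 2.24 ± 0.694, 2.85 ± 0.575 and 2.71 ± 0.723 (log2 0.34, SE 0.42 at 5 Gy; 0.66 without 0 Gy replicate 1, 0.52 without 5 Gy replicate 2, 0.14 without 0 Gy replicate 2 and 0.18 without 5 Gy replicate 3). PLOD2 hsa_circ_0122319, from a collagen lysyl hydroxylase gene, stood at 2.57 ± 0.330, 2.43 ± 0.513 and 1.41 ± 0.300 (log2 -0.89, SE 0.49, p 0.0715 at 5 Gy). ZBTB44 hsa_circ_0002484 stood at 1.70 ± 0.460, 2.58 ± 1.38 and 2.87 ± 0.820 (log2 0.79, SE 0.46, p 0.0870), and ZKSCAN1 hsa_circ_0001727 at 1.61 ± 0.183, 2.37 ± 0.575 and 2.66 ± 1.07 (log2 0.69, SE 0.47; 0.32 without 5 Gy replicate 1). edgeR called 0 of 28 at 5 against 0 Gy, with 1 at an unadjusted p under 0.05 (XPO1), and DESeq2 called 0 with 1 and the exact test, over 16 circRNAs, 0 with 0. Of the 28, 12 were higher and 16 lower, and 4 had groups that did not overlap (chance 10%). In the 738, edgeR called 0 with 35 at an unadjusted p under 0.05 (36.9 expected), and DESeq2 called 0 with 11. Without 0 Gy replicate 2, XPO1 hsa_circ_0001016 reached an adjusted p of 0.0381 over the same 28 circRNAs, the lowest of its 16 alternatives, of which the highest was 0.782. With the filter applied again after that library was left out, 34 circRNAs were tested, 0 were called by edgeR with 2 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0907.

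**Figure D1:**
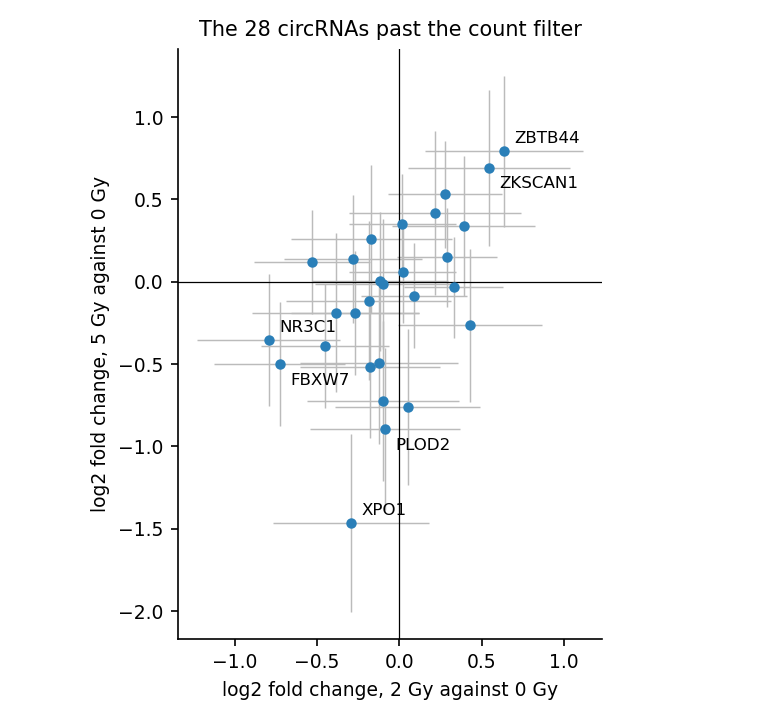
Log2 fold change at 5 against 0 Gy (vertical) by that at 2 against 0 Gy (horizontal) for the 28 tested circRNAs; points are edgeR estimates and bars 1 SE. XPO1 hsa_circ_0001016 lies lowest at -1.47, and the 0 Gy libraries are shared by both axes.

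Between 5 and 2 Gy, and along the dose, the same XPO1 circle had the lowest p among the 28. XPO1 hsa_circ_0001016 differed by -1.17 in log2 between 5 and 2 Gy (SE 0.55, p 0.0339, adjusted p 0.596; over the 738 -0.66 without 2 Gy replicate 2 and -0.69 without 5 Gy replicate 3), and fell by 0.29 per Gy in the estimate of the trend (SE 0.10, p 0.00629, adjusted p 0.176). PLOD2 hsa_circ_0122319 had a slope of -0.18 per Gy (p 0.0445, adjusted p 0.584). KANSL1 hsa_circ_0005455 stood at 2.74 ± 0.601 at 2 Gy and 4.41 ± 0.601 at 5 Gy (log2 0.65, SE 0.33, p 0.0513). The PHIP circle on chromosome 6 (79707131 to 79714153) and UBE3A hsa_circ_0000586 had log2 differences of -0.81 (p 0.0797) and -0.69 (p 0.106) between 5 and 2 Gy. edgeR called 0 of 28 for 5 against 2 Gy and 0 for the trend, with 1 and 2 at an unadjusted p under 0.05, and DESeq2 called 0 and 0 with 0 and 1. The exact test between 5 and 2 Gy, over 26 circRNAs, called 0 with 2 at that level. Among the 738, edgeR called 0 and 0, with 28 and 29 at that level.

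The fold changes at 2 and 5 Gy share the 0 Gy libraries, which alone makes them correlate. Across the 28 circRNAs, which are not independent replicates, Pearson r was 0.517, against 0.512 (0.227 to 0.777) in simulated groups without any change, and the covariance was 0.0930 against 0.0892. Across the 738 it was 0.632 against 0.574 (0.503 to 0.624), with a covariance of 1.28 against 0.896 (0.708 to 1.07), a difference of 0.379. With an unadjusted p under 0.05, 13 circRNAs were higher at both doses, of 27 at 2 Gy and 24 at 5 Gy, where independence gives 0.878 and the simulation 6.14 (up to 11.5). The count lower at both doses was 0 of 10 and 11 (edgeR, 0 called after adjustment in either), where independence gives 0.149 and the simulation 0.860. The simulation gave all circRNAs 1 common dispersion (0.181 over the 738). Real circRNAs and libraries may vary unequally, so values outside its range cannot be read as a shared response. The 3 control libraries were too few to be divided between the doses.

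Reads were also summed over all circRNAs of a host gene. PCMTD1 summed over its 2 circRNAs stood at 0.649 ± 0.367, 2.93 ± 0.445 and 0.763 ± 0.581 per 1000, 4.25-fold at 2 against 0 Gy (log2 2.09, SE 0.65, p 0.00156, adjusted p 0.0905). The sum met the minimum count in the 2 Gy libraries only, so it too entered the test through the dose where it was high. DLG1, a scaffold protein gene, had log2 0.95 (SE 0.40, p 0.0178) at 2 Gy, MALAT1, an abundant nuclear long noncoding RNA, -0.94 (SE 0.40, p 0.0183, and -0.60 without 0 Gy replicate 1), NFATC3, a calcineurin-dependent transcription factor gene, 0.89 (SE 0.39, p 0.0240), and FOCAD 1.18 (SE 0.54, p 0.0285). At 5 Gy NFATC3 had log2 1.04 (SE 0.38, p 0.00636, adjusted p 0.369), MBNL1, a splicing regulator gene, -1.05 (SE 0.50, p 0.0373, but -0.62 without 5 Gy replicate 1 and -1.83 without 5 Gy replicate 3), FAM13B 0.87 (SE 0.42, p 0.0388), DLG1 0.77 (SE 0.40) and FBXW7 -0.69 (SE 0.37). edgeR called 0 of 58 host genes at 2 Gy and 0 at 5 Gy, with 6 and 3 at an unadjusted p under 0.05, and DESeq2 called 0 and 0, with 2 and 1. Chance gives a share of 0.05 of the 58 at that level. Without 5 Gy replicate 1, over the same 58 genes, the PCMTD1 sum at 2 Gy passed with an adjusted p of 0.00709, the lowest of its 15 alternatives, of which the highest was 0.983. With the filter applied again, 77 host genes were tested without that library and edgeR called 0, with 6 at an unadjusted p under 0.05 and a smallest adjusted p of 0.225.

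The share of reads from XPO1 hsa_circ_0001016 among both tested XPO1 circles, a measure chosen after the levels were seen, was 54.0 ± 8.24, 43.5 ± 13.5 and 26.6 ± 14.4% at 0, 2 and 5 Gy. Pearson r with dose was -0.745 (exact permutation p 0.0190) and Spearman rho -0.767 (p 0.025), and without 5 Gy replicates 1 and 2 r was -0.837. Here and below those 2 libraries were left out by a rule on dose and order, not for their values. The 5 Gy library left, replicate 3, had the lowest share, 10% against 36.4 and 33.3% in replicates 1 and 2. This was a single relation, computed because of the level. The difference between 5 and 0 Gy had an exact p of 0.1, the smallest that 3 against 3 libraries allow. A test of circRNA usage within each of 113 host genes, also chosen afterwards, gave XPO1 a p of 0.138 at 5 Gy (adjusted p 0.526) and ZFAND6 a p of 0.00569 at 2 Gy and 0.00509 at 5 Gy (adjusted p 0.259 and 0.287). edgeR called 0 hosts in each comparison, with 13 at 2 Gy and 10 at 5 Gy at an unadjusted p under 0.05. Chance gives a share of 0.05 of the 113 hosts at that level, which both counts exceed.

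**Figure D2:**
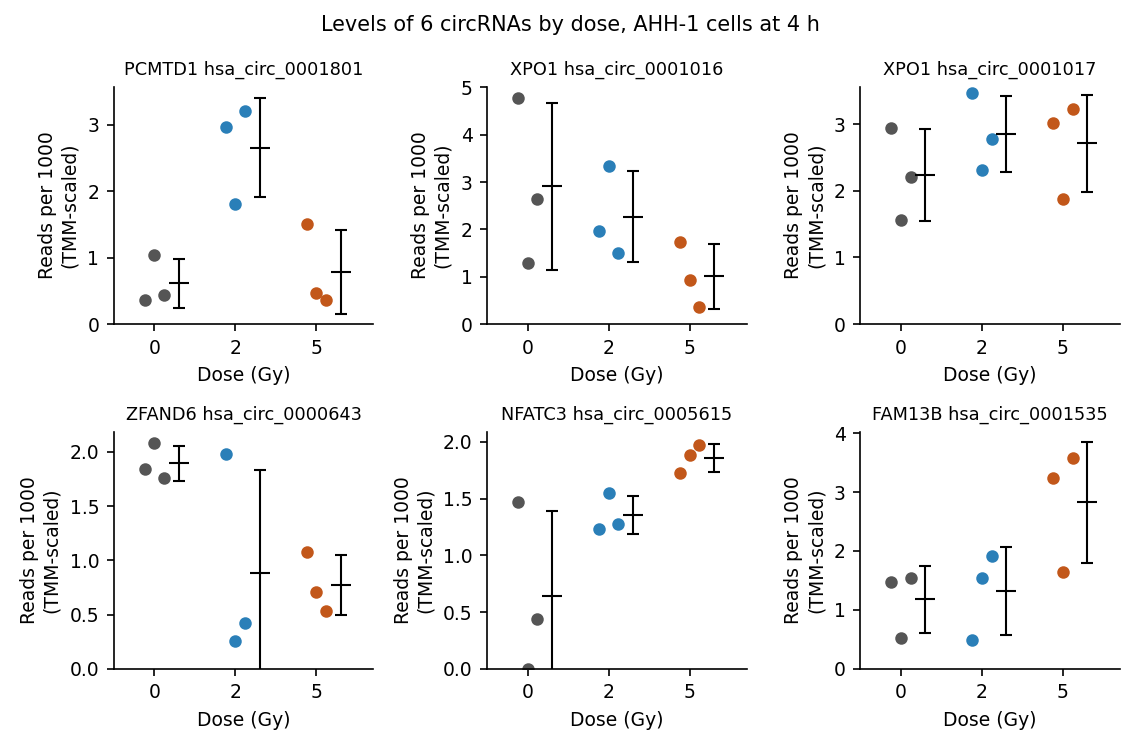
Reads per 1000 back-splice reads after TMM scaling (vertical) by dose in Gy (horizontal) for 6 circRNAs; points are libraries (replicates 1 to 3 from left), dashes means and bars SD, drawn down to 0 where they pass it. PCMTD1 hsa_circ_0001801 stood at 2.66 ± 0.748 at 2 Gy against 0.616 ± 0.368 at 0 Gy, and XPO1 hsa_circ_0001016 at 1.01 ± 0.687 at 5 Gy against 2.91 ± 1.76.

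The authors' deposited table for 2 Gy names PCMTD1 hsa_circ_0001801 among 7 differential circRNAs of 71 listed, 3 higher and 4 lower, and it was the single one of the 7 with an adjusted p under 0.05 there (log2 1.94, 3.85-fold, adjusted p 0.0404). The other 6 in the authors' deposited table were UHRF2 (log2 1.27), SPECC1 (1.11), FBXW7 hsa_circ_0001451 (-0.81), hsa_circ_0092938 with no gene named (-1.17), ZFAND6 (-1.18) and ZDHHC21 (-1.47), with adjusted p from 0.379 to 0.507. For 5 Gy the authors' deposited table lists 68, of which 8 are differential: NFATC3 (1.71), BARD1 (1.38), FAM13B (1.27), MPP6 (1.22), ATP5F1C (1.11), PLOD2 (-0.91), ZFAND6 (-1.29) and XPO1 hsa_circ_0001016 (-1.49). None of these 8 has an adjusted p under 0.05 in the authors' deposited table, where all 8 have an unadjusted p under 0.05 and the smallest adjusted p is 0.159. The same tables carry an outlier mark for 2 of the 7 and 6 of the 8.

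In the refit over 738 circRNAs all 7 and all 8 had the sign of the authors' deposited table, 2 and 5 had an unadjusted edgeR p under 0.05, and 0 and 0 passed adjustment (DESeq2 over the 738 called 0 in each comparison). NFATC3 hsa_circ_0005615 (chromosome 16, 68155890 to 68157024) stood at 0.638 ± 0.756, 1.35 ± 0.168 and 1.86 ± 0.123 per 1000 (log2 1.73, SE 0.68, p 0.0111 at 5 Gy), and FAM13B hsa_circ_0001535 (chromosome 5, 137320946 to 137324004) at 1.18 ± 0.571, 1.32 ± 0.739 and 2.82 ± 1.03 (log2 1.29, SE 0.52, p 0.0129). BARD1 hsa_circ_0001098, from the gene of the BRCA1 partner, stood at 0.540 ± 0.551 and 1.74 ± 0.986 at 0 and 5 Gy (log2 1.41, SE 0.68, p 0.0376). ZFAND6 hsa_circ_0000643 (chromosome 15, 80412670 to 80415142) stood at 1.89 ± 0.165, 0.887 ± 0.948 and 0.774 ± 0.278, and had log2 -1.14 (SE 0.64, p 0.0774) at 2 Gy and -1.26 (SE 0.64, p 0.0496) at 5 Gy. ZDHHC21 hsa_circ_0008952, from a palmitoyltransferase gene, stood at 1.92 ± 0.330 and 0.692 ± 0.324 at 0 and 2 Gy (log2 -1.43, SE 0.63, p 0.0239). UHRF2 hsa_circ_0002359 and SPECC1 hsa_circ_0000745 had log2 1.32 (SE 0.68) and 1.16 (SE 0.62) at 2 Gy, and MPP6 hsa_circ_0001685 and ATP5F1C hsa_circ_0007292 had 1.27 (SE 0.77) and 1.14 (SE 0.63) at 5 Gy. Single libraries moved several of these values. NFATC3 had log2 2.78 without 0 Gy replicate 1 and 1.13 (p 0.115) without 0 Gy replicate 2. BARD1 had 2.48 without 0 Gy replicate 3, 0.94 without 0 Gy replicate 1 and 0.92 (p 0.272) without 5 Gy replicate 2. ZFAND6 at 2 Gy had -2.25 without 2 Gy replicate 1, -0.66 without 2 Gy replicate 2 and -0.71 without 2 Gy replicate 3, and its p at 5 Gy lay between 0.0504 and 0.176 over the libraries left out. MPP6 at 5 Gy had 2.36 without 0 Gy replicate 2 and 0.86 without 0 Gy replicate 3. The p of ZDHHC21 at 2 Gy rose to 0.111 at most (without 2 Gy replicate 1), and that of FAM13B to 0.11 (without 0 Gy replicate 2, log2 0.92). Across the 28 tested circRNAs, which are not independent replicates, log2 fold changes of the authors' deposited table and of the refit had a Pearson r of 0.999 at 2 Gy and 1.00 at 5 Gy. Both come from the same counts by edgeR with TMM scaling, so this r and the shared signs were bound to follow and are no replication.

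By annotated junction class, a grouping chosen after the data were seen, intron-intron circRNAs took a smaller part of the reads in irradiated libraries. Exon-exon circRNAs took a larger one. Irradiated libraries also tended to hold more back-splice reads. Intron-intron circRNAs (1546 circRNAs, 3926 reads) took 13.6 ± 2.29, 9.53 ± 1.5 and 8.83 ± 0.829% at 0, 2 and 5 Gy, and exon-exon circRNAs (5374 circRNAs, 30750 reads) 76.5 ± 2.60, 82.2 ± 1.38 and 81.9 ± 1.59%. Intergenic-intergenic circRNAs took 4.00 ± 0.219, 2.89 ± 0.307 and 3.61 ± 0.828%, and circRNAs with a circBase ID 70.8 ± 2.21, 76.0 ± 1.10 and 75.7 ± 1.71%. All 6 irradiated libraries lay below all 3 of 0 Gy for intron-intron circRNAs, a difference of -4.45 percentage points (two-sided exact permutation p 0.0119, the smallest that 6 against 3 libraries allow, adjusted 0.0198 over 5 measures). Pooling 2 and 5 Gy was not a planned test, and each dose alone against 0 Gy gave an exact permutation p of 0.1. The 5 measures are shares of the same reads and not independent, so the adjusted values may count 1 shift more than once. The nearest libraries were 0 Gy replicate 3 at 12.2% (95% Wilson interval 11.3 to 13.3%) and 2 Gy replicate 2 at 10.7% (9.71 to 11.7%). The smallest library, 0 Gy replicate 1, had 16.3% (14.9 to 17.7%) against 12.4% (11.4 to 13.4%) in 0 Gy replicate 2, and without it the difference was -3.13 points (exact p 0.0357). These intervals cover counting error only, and libraries of the same dose differed by more than that. Exon-exon circRNAs differed by 5.53 points (exact p 0.0119, adjusted 0.0198), circBase-listed ones by 5.08 points (exact p 0.0119, adjusted 0.0198), junctions with mixed ends by -0.329 points (exact p 0.0357, adjusted 0.0446) and intergenic ones by -0.747 points (exact p 0.119). Between 5 and 2 Gy intron-intron shares did not differ beyond the replicates (exact p 0.6). The intron-intron share correlated with dose at r -0.739 (exact permutation p 0.0179, adjusted 0.0794) and rho -0.791 (p 0.0214), and without 5 Gy replicates 1 and 2 at r -0.777 (p 0.05). The circRNA caller is not given in the sources used here, so false junctions could not be counted. Intron-intron reads numbered 446, 496 and 522 at 0 Gy, 411, 397 and 386 at 2 Gy, and 474, 381 and 413 at 5 Gy. They thus did not rise with the library totals, which ran from 2742 to 5201 reads, as exon-exon reads did (2017 to 4330). The relation of the intron-intron share with library totals was not tested, so the shift cannot be credited to dose alone.

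**Figure D3:**
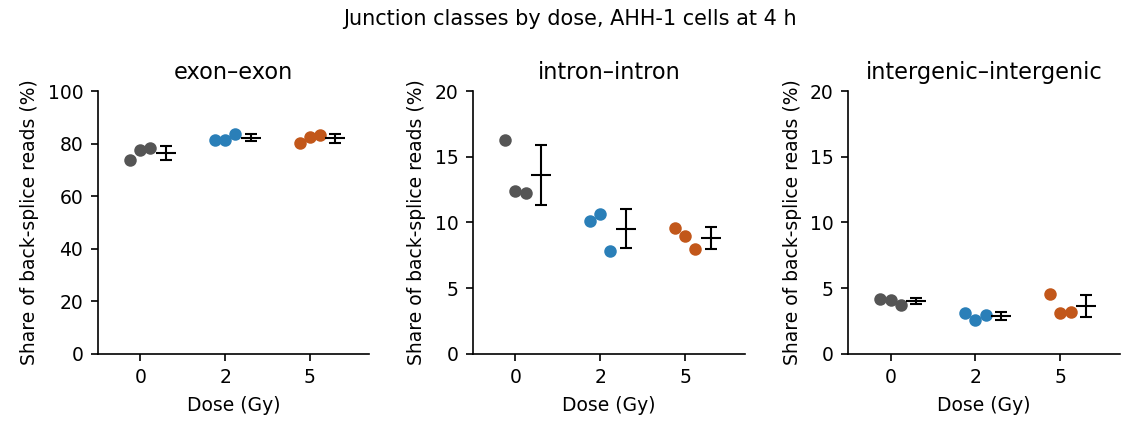
Share of back-splice reads in percent (vertical) by dose in Gy (horizontal) for exon-exon, intron-intron and intergenic-intergenic circRNAs; points are libraries (replicates 1 to 3 from left), dashes means and bars SD, and the vertical scale of the exon-exon panel differs. The intron-intron share was 13.6 ± 2.29% at 0 Gy against 9.53 ± 1.5% at 2 Gy and 8.83 ± 0.829% at 5 Gy.

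Total back-splice reads were 3672 ± 816, 4243 ± 622 and 4801 ± 489 at 0, 2 and 5 Gy, and the number of circRNAs detected after thinning to 2742 reads was 1458 ± 117, 1511 ± 42.4 and 1581 ± 21.1. With dose, totals had r 0.647 (exact permutation p 0.0565) and rho 0.632 (p 0.0893), and r 0.680 without 5 Gy replicates 1 and 2. As CPM of the library totals implied by the deposited CPM table, a scaling chosen after the data were seen, back-splice reads made up 91.4 ± 6.38, 92.9 ± 6.52 and 89.7 ± 5.08, with r -0.157 (exact permutation p 0.673), rho -0.105 (p 0.833) and r -0.127 without those 2 libraries. The implied totals themselves were 4.00e+07, 4.60e+07 and 5.35e+07 on average at 0, 2 and 5 Gy (r 0.691, exact permutation p 0.0393). The rise in total back-splice reads thus went with larger libraries. Detected circRNAs had r 0.645 (exact permutation p 0.0375) and rho 0.685 (p 0.0607), and r 0.556 (p 0.207) without the same libraries. The share of the 10 most abundant circRNAs had r 0.229 (exact permutation p 0.559) and rho 0.0527 (p 0.955), and r 0.398 without them. Adjusted over these 3 measures the p-values of r were 0.0848, 0.0848 and 0.559. The relation of detected circRNAs with dose reversed to r -0.651 (exact p 0.0452) when 2 reads were asked for, and to -0.492 (exact p 0.173) when the thinned libraries were filtered again, an alternative chosen after the data were seen. These negative values went with the library totals, since thinning leaves the smallest library whole. Thinned only, the r without 0 Gy replicate 1 was 0.673 (exact p 0.0821).

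Grouped by host-gene function, no list passed as a set. The 28 circRNAs of cell cycle and mitosis genes among the 738 were lower in 21 and higher in 7 at 5 Gy, with a median log2 of -0.33 (camera p 0.0356, adjusted 0.320; with the correlation estimated 0.0561, adjusted 0.504), and lower with dose in the trend (p 0.0282, adjusted 0.254; with the correlation estimated 0.0429, adjusted 0.386). Over all 308 circRNAs of these genes the share of reads was 3.65 ± 0.101, 3.74 ± 0.181 and 3.64 ± 0.377% at 0, 2 and 5 Gy. DNA damage signalling and repair genes (27 circRNAs) were higher in 8 and lower in 19 at 2 Gy, and higher in 15 and lower in 12 at 5 Gy. p53 targets (5) were higher in 3 and 2, NF-κB and innate immune genes (11) in 5 and 2, B-lymphoid genes (6) in 3 and 2, chromatin modifiers (40) in 20 and 18, RNA processing genes (28) in 14 and 13, and ubiquitin ligases and deubiquitinases (33) in 15 and 16, at 2 and 5 Gy. For p53 targets at 5 Gy the median was -0.28 and the mean 0.14. Hosts of widely reported circRNAs (95 among the 738) were higher in 51 and 48, and their 11 members among the 28 gave camera p-values of 0.603 at 2 Gy and 0.895 at 5 Gy. camera with the preset correlation called 0 lists in every comparison, and 0 with the correlation estimated. The smallest p of fry over the 9 lists and 4 tests, not adjusted, was 0.0188 for ubiquitin ligases and deubiquitinases between 5 and 2 Gy, where camera gave 0.0953. edgeR called 0 members over all circRNAs and 0 adjusted over the list alone in each of the 9 lists tested; with a replicate block 1 of the 11 members among the 28 passed at 5 Gy and 1 for the trend, adjusted over the list alone (0.0463 and 0.0432).

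The share of reads from B-lymphoid host genes, one of 11 list shares computed after the data were seen, was 1.28 ± 0.153, 1.15 ± 0.108 and 0.956 ± 0.0949% at 0, 2 and 5 Gy. Its r with dose was -0.806 (exact permutation p 0.0107, adjusted 0.118) and rho -0.738 (p 0.0369), and without 5 Gy replicates 1 and 2 r was -0.752 (p 0.0643). Hosts of widely reported circRNAs took 11.2 ± 0.909, 12.1 ± 0.158 and 12.2 ± 0.499% (irradiated against 0 Gy, exact p 0.0238, adjusted 0.262). T and NK cell genes held 8 reads in 4 circRNAs and myeloid genes 6 reads in 3 circRNAs over the 9 libraries. The p-values throughout measure the spread between these libraries, which the labels do not describe as separate cultures.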

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

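The tests here were chosen after the result was seen, except the thinning test, which was set before its outcome was seen. Exon-exon circRNAs took 5.53 percentage points more of the back-splice reads in irradiated libraries than at 0 Gy (82.1 ± 1.34% of 6 libraries against 76.5 ± 2.60% of 3), and no comparison fixed in advance used the annotated junction class. It was noted as a signal outside the planned measurement and above the level in the control libraries. Its counterpart was a lower share of intron-intron circRNAs, 9.18 ± 1.15% against 13.6 ± 2.29%.

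After thinning to the smallest total and filtering again, the intron-intron difference was -5.03 points, with all 6 irradiated libraries below all 3 of 0 Gy. That test cannot decide on depth. It left the smallest library, 0 Gy replicate 1, whole (16.7% afterwards). Larger libraries lost junctions at the minimum of 2 reads (5 Gy replicate 3 from 7.94 to 6.05%). Libraries of like total still differed. With 4007 and 4267 reads, 0 Gy replicates 2 and 3 had 12.4 and 12.2%. The share was 10.1% in 2 Gy replicate 1 (4071 reads) and 8.95% in 5 Gy replicate 2 (4255 reads). Junctions seen in 1 library only do not explain all of the intron-intron difference. Among circRNAs seen in at least 2 libraries it was -1.80 points (3.05 against 4.86% at 0 Gy), again without overlap. Among those seen in at least 3 libraries it was -1.31 points (2.42 against 3.73%) and the groups overlapped (exact p 0.0238). These shares start from a lower base than the 13.6% of all circRNAs, so their points cannot be compared directly with -4.45. The share of reads in circRNAs seen in 1 library was itself lower after irradiation, 27.0 ± 1.42% against 30.1 ± 0.967% (exact p 0.0238), so such junctions may carry part of the -4.45 points. A technical explanation that stays open is that 0 Gy libraries held more junctions with both ends outside annotated exons. Junctions with mixed ends differed little, 5.52 ± 0.123% in irradiated libraries against 5.84 ± 0.217%. The intergenic share of 5 Gy replicate 1, 4.57%, lay above all 0 Gy libraries. The log2 ratio of the intergenic share was -0.30 (SE 0.14) and that of the intron-intron share -0.57 (SE 0.16), a difference of 0.27 (SE 0.19), within 2 of its standard errors. A loss of intron-containing circles after irradiation may also be the cause, but the labels give no batch, and a batch that followed the dose groups would leave the same pattern.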

How the results depend on the processing

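The settings chosen after the data were seen are the minimum count in 2 instead of 3 libraries, the library sizes implied by the deposited CPM, DESeq2 on the 738, the refits of the deposited tables, the block for the correlation and for the deposited fold changes, the 738 for those fold changes, camera with estimated correlation on the 738, thinning followed by a second filter, back-splice reads as CPM of the implied totals, and the class shares.

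Of the values that answer a comparison, 152 kept their direction and side of the threshold, 5 became weaker, 4 stronger, 23 moved and 2 reversed. Of the values of named circRNAs and host genes, 1288 did so and 2 became stronger. The 97 that moved took the opposite sign, as GUSBP1 hsa_circ_0128780 at 2 Gy did in 9 of its 16 alternatives, and 0 reversed past a threshold. Calls of edgeR ranged over the libraries left out from 0 to 1 at 2 Gy and from 0 to 1 between 5 and 2 Gy, and were 0 for 5 against 0 Gy, the trend and both host-gene comparisons, with the filter applied again each time. The minimum count in 2 libraries gave 1 call at 2 Gy. All these calls were PCMTD1, which is not among the 28. With the tested sets fixed, XPO1 hsa_circ_0001016 was called at 5 Gy without 0 Gy replicate 2 (adjusted p 0.0381, against 0.0907 filtered again) and the PCMTD1 sum at 2 Gy without 5 Gy replicate 1 (0.00709, against 0.225 filtered again).

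The correlation of the 2 and 5 Gy fold changes was 0.632 with at least 2 reads in at least 3 libraries, where the value simulated without any change also rose, from 0.512 to 0.574, and 0.270 to 0.653 without single libraries. Deposited and refitted fold changes correlated at 0.891 to 1.00 at 2 Gy and 0.907 to 1.00 at 5 Gy without single libraries, since the deposited values use all of them. The replicate block gave 0.506 for the first correlation and 0.996 and 0.998 for the others, and changed no call over all circRNAs or host genes; adjusted over the list alone it gave 1 call among the widely reported circRNAs at 5 Gy and 1 for the trend.

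Detected circRNAs correlated with dose at -0.651 with at least 2 reads at the common depth and -0.492 when thinned and filtered again. The thinned count keeps circRNAs that met the minimum of 2 reads only at full depth, which favours deeper libraries. Filtering again took the smallest library, 0 Gy replicate 1, from 1323 to 1171 circRNAs and the largest, 5 Gy replicate 3, from 1590 to 1050. The positive r thus depended on depth through that minimum. With at least 2 reads the count was 855 in 0 Gy replicate 1, which thinning left whole. It was 755 in 2 Gy replicate 2, the next smallest library, and 655 in 5 Gy replicate 3. The negative r thus also went with the library totals and cannot be read as an effect of dose. The r of the thinned count was 0.597 to 0.731 without single libraries, and its exact p exceeded 0.05 without 0 Gy replicate 1 (0.0821), 2 Gy replicate 1 (0.0536) or 5 Gy replicate 1, 2 or 3 (0.118, 0.0839 and 0.120). Total reads gave -0.157 as CPM of the implied totals, and 0.547 to 0.724 without single libraries (exact p 0.0375 without 0 Gy replicate 3, 0.0446 without 2 Gy replicate 3 and 0.0446 without 5 Gy replicate 2). The implied totals themselves rose with dose (r 0.691, exact permutation p 0.0393), so the rise in total reads went with larger libraries. The share of the 10 most abundant gave -0.0103 to 0.484, and the cause of that range was not tested. The intron-intron difference was -5.15 (without 0 Gy replicate 3) to -3.13 points (without 0 Gy replicate 1). The median SE was 0.43 at 2 Gy among the 28 circRNAs and 1.33 among the 738, and for 5 against 0 Gy simulated 4-fold changes were recovered in 95 and 13.1%; depth and a lack of true changes were not separated as reasons for few calls. Every alternative set in advance was run.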

Other observations

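The use of these tests to weigh PCMTD1 and XPO1, the usage test, the filter over 36 circRNAs and the splits were chosen after the result was seen, while the fits over the 738 and without single libraries were set in advance. PCMTD1 hsa_circ_0001801 was higher at 2 Gy than at 0 Gy, and the difference between 5 and 2 Gy had an unadjusted p of 0.00308 and an adjusted p of 0.990. The difference did not come from 1 library alone, although calls changed with the library left out: the largest unadjusted edgeR p over the 9 fits that leave out a library was 0.0125 among the 738. The circRNA was picked for its low p in these same libraries, so this says nothing about chance. Chance among many tests cannot be told apart from a change: the adjusted p was 0.846 over 738 circRNAs and 0.0381 over 36. A response at the lower dose may be biological, and no further test of it was run.

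XPO1 hsa_circ_0001016 was lower at 5 Gy while hsa_circ_0001017 was not, a log2 difference of -1.80 (SE 0.69). A fall of all XPO1 circles would make both fall, but the test of usage over the 5 XPO1 circRNAs had a p of 0.138, so a fall of all and a fall of 1 cannot be told apart with these counts. The adjusted p of that test was 0.526, which chance among 113 host genes could give.

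For the comparisons of 3 against 3 libraries, the 10 splits are too few to give a share under 0.05. The real number of calls was 0 and the highest of the other splits 0 for circRNAs at 2 against 0, 5 against 0 and 5 against 2 Gy, and for host genes at 2 and at 5 Gy. For the dose trend, 100 of 100 splits gave as many calls as the real 0, with a highest other of 2, and a real count of 0 leaves no room for another outcome, so these counts say nothing about chance.

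MALAT1 gave more back-splice junctions than any other host, 31, all annotated exon-exon, of which 19 were seen in 1 library and 5 had a circBase ID, with 111 reads in all. Of the 7902 circRNAs, 52.1% had a circBase ID, the median spliced length was 525 nucleotides, and 1860 host genes had 1 circRNA.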
